A study of Homo sapiens with 33 samples.

How the data were processed

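Read counts per gene were analysed for 14 RNA libraries of CNCCs derived from H9 embryonic stem cells, 3 WT and 4 FHS lines in each of 2 differentiations. RNA was taken at passage 5 on fibronectin from independent differentiations, purified by poly(A) selection, primed with random hexamers and sequenced as single-end reads of 75 bp on a NextSeq, per the labels' protocols. A further 19 samples of V5 ChIP, for tagged H2A.Z and untagged controls per the labels, are not analysed here.

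The deposited values are whole-number counts of reads per gene, made with featureCounts 1.4.6-p2 on exons grouped by gene name in GENCODE release 24, with a mapping quality of at least 10 and primary alignments alone, per the file headers. No strand option was set, per the file headers, and the labels' protocols describe no step that marks the strand, so reads of a gene and of an antisense or overlapping gene cannot be told apart. Genes with near-identical copies, such as histones, ribosomal proteins and protocadherins, may have lost reads to the mapping quality filter and their levels are uncertain. Per the submitters' processing notes the build was hg19, while the headers name GENCODE release 24, which annotates GRCh38. The notes also name cutadapt, Bowtie2, HISAT2, featureCounts, Subread, DESeq2, MACS2 and bedtools, without versions. The aligner and the build used for each RNA library are not given in the sources used here. Coordinates are those of the count files. Each file held 58684 genes.

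The 11 libraries used had totals of 4124475 to 27399925 counts. The libraries of WT line 2, WT line 3 and FHS line 1 of differentiation 1 were left out because more than 20 of the 100 genes with the highest median CPM had 0 reads in them. That limit was set after the counts were seen and departs from the design, in which none of the 14 libraries was left out. The comparison within differentiation 2 kept all of its libraries. Fits with the 14 are among the alternatives. The file headers give WT line 3 a different clone code in each round, and the line number in the labels was followed.

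Tests used R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries scaled by TMM, and fitted with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The comparisons were WT against FHS on counts summed per line, WT against FHS within each differentiation, the interaction of genotype and differentiation with the line as a block, and differentiation 2 against 1 with genotype as a term. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values use the TMM factors of the comparison they belong to. Gene lists, 32 in number, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, for lists with at least 5 tested genes; camera with an estimated correlation and fry were run beside it. Of the 765 list members 764 matched a gene of the files, 2 of them through an older or newer symbol. The comparisons, tests, lists, naming rule and alternatives, other than those said below to be added, were fixed before the data were examined.

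Genes were named by rule. For genotype these were the 12 largest rises and 12 largest falls past the threshold with a mean of at least 2 CPM in 1 group, no overlap between WT and FHS lines and the same sign in both differentiations, leaving out unnamed clones, long intergenic, micro and small nucleolar RNA genes, pseudogenes and genes used to tell sex. The rule was written for the line sums, where no gene passed, so there the 6 smallest p in each direction are named, taken among genes over the floor of 2 CPM whose lines did not overlap, a condition added to the rule. After the counts were seen, the rule and the list tests were applied to differentiation 2 as well. For each list the rule gave up to 4 members past the threshold with the largest change, or up to 2 with the smallest p where fewer than 2 passed. SRCAP, H2AFZ, H2AFV, TWIST1, SOX9 and TFAP2A were always given. Some genes that met the rule, and 1 list, are not named, with no gene or list in their place. For the rounds it gave the 6 largest in each direction with the same sign in each line, which could be asked only of the 4 lines with both rounds; the list rule was applied to the rounds as well after the counts were seen.

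The labels use the same line numbers in both rounds, which was taken to mean the same lines. They do not state this, and they word the names of the WT lines differently in each round. The line sums, the interaction and the concordance rest on this reading. The deviations of FHS lines 2, 3 and 4 from their mean log2 CPM had correlations across genes of 0.397, 0.279 and 0.121 between rounds. The blocked count is therefore given beside the comparison of the rounds. The unblocked fit came first in the design. Alternatives were DESeq2 1.42.0, other scaling factors, no filter, a filter of at least 5 CPM in 3 samples, a threshold of 0.1, robust fitting, each line left out, line numbers as a block, libraries in place of line sums, limma voom with the line as a random effect, limma-trend on line means, and, added after the data were seen, the 14 libraries and the omission of chromosome 17. 

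The fits were tested on simulated negative binomial counts at the real means and library sizes, with 200 changed genes and a dispersion of 0.03 for differentiation 2 and 0.1 for the other designs. In the design of differentiation 2, with 15128 genes, edgeR recovered 84% of changes of 2-fold and 100% of those of 4-fold and called 10 unchanged genes. It recovered 27% and 94% for the line sums (16875 genes), 42% and 99% for the rounds (17161 genes), 2% and 37% for differentiation 1 (17917 genes) and 1% and 0% for the interaction (18894 genes). Intervals and bounds cover counting error only.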

Results

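The series followed human cranial neural crest cells (CNCCs), the migratory embryonic cells that give rise to much of the face, made in culture from the H9 embryonic stem cell line. The stem cells carried a CRISPR edit of SRCAP, the ATPase of a complex that places the histone variant H2A.Z into nucleosomes. In the WT lines the edit added a FLAG-HA tag to the end of the normal protein. In the FHS lines it put the tag on a truncating SRCAP allele of the kind seen in Floating-Harbor syndrome, a disorder of growth, speech and facial shape. Polyadenylated RNA was counted per gene in 3 WT and 4 FHS lines, numbered alike in each of 2 rounds of differentiation, which gave 14 libraries. The comparisons asked which genes differed between WT and FHS CNCCs, whether they did so in both rounds, and how far the rounds themselves differed.

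Of the 14 libraries, 11 gave between 4124475 and 27399925 reads on genes and had reads on 21699 to 28776 genes. The libraries of WT line 2, WT line 3 and FHS line 1 from differentiation 1 had 2505654 to 3537093 reads on 9191 to 9282 genes. In them GAPDH, VIM, SOX9, FN1 and COL1A1, which neural crest cells express at a high level, had 0 reads. Of the 100 most abundant genes, 63, 61 and 63 had 0 reads in these 3 libraries and none had 0 reads in any of the other 11. Their rank correlation across genes with the other libraries was 0.257 to 0.286, against 0.877 to 0.944 among the 11. They were left out of every comparison, so differentiation 1 kept 1 WT and 3 FHS lines, and differentiation 2 kept all 3 WT and 4 FHS lines. Values are CPM after TMM scaling, as mean ± SD over lines. Log2 fold changes carry their standard error. The edgeR p-values of genotype, on line sums or within a round, measure the spread between clonal lines of 1 parent cell line. Those of the interaction measure the spread within lines. Those between rounds treat the libraries as separate samples, although some lines enter both rounds. Camera compares the genes of a list with the other genes. Fisher's exact test, used for chromosome 17, treats neighbouring genes as independent. Neither of these measures the spread between lines. The libraries of a genotype within a round differed by more than counting noise in each pair tested (chi-square per degree of freedom of 3.24 or more).

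**Figure D1:**
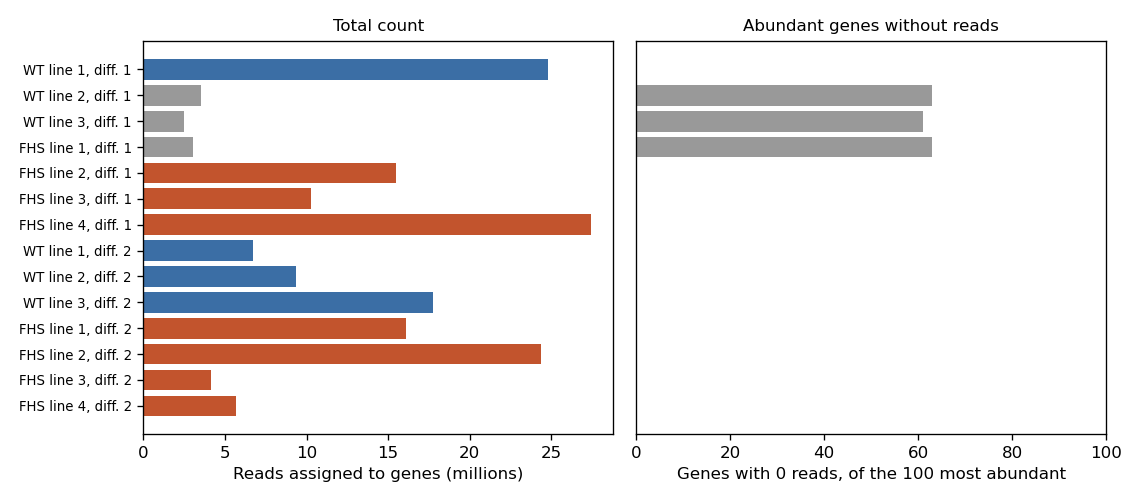
Total reads assigned to genes (left) and how many of the 100 most abundant genes had 0 reads (right) in each library, with WT in blue, FHS in orange and the libraries left out in grey. The 3 grey libraries had 61 to 63 of these genes at 0, and the other 11 had none.

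SRCAP, the edited gene (chromosome 16, 30698209 to 30741409 on GRCh38), was read in each of the libraries used. In differentiation 2 it stood at 5.69, 14.7 and 7.65 CPM in WT lines 1, 2 and 3 and at 9.63, 7.72, 11.1 and 481 CPM in FHS lines 1, 2, 3 and 4. In differentiation 1 it stood at 6.00 CPM in WT line 1 and at 6.07, 15.6 and 9.38 CPM in FHS lines 2, 3 and 4. Counts per gene do not show the edit, so these values do not check the genotype labels. The log2 fold change of SRCAP in differentiation 2 was 3.72 ± 1.5 (edgeR adjusted p = 0.176, n = 3 and 4), and it was -0.02 without FHS line 4. The genes of H2A.Z itself did not pass the test. H2AFZ had 251 ± 9.46 CPM in WT and 228 ± 14.3 CPM in FHS (edgeR adjusted p = 0.287), and H2AFV had 191 ± 0.869 and 198 ± 3.18 CPM (edgeR adjusted p = 0.675). Of the 19 tested genes of the SRCAP complex and H2A.Z exchange, 0 passed edgeR's test over all genes and 0 adjusted over the list alone, and camera gave the list an adjusted p of 0.632.

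In differentiation 2, PAX7, a marker of early neural crest (chromosome 1, 18631006 to 18748866), fell from 38.5 ± 5.62 CPM in WT (n = 3) to 4.22 ± 0.617 CPM in FHS (n = 4), a log2 fold change of -3.15 ± 0.15 (edgeR adjusted p = 1.16e-05). ZIC2 (chromosome 13, 99981772 to 99986773) fell from 59.7 ± 7.09 to 11 ± 2.99 CPM and its relative ZIC1 from 35.8 ± 11.7 to 7.22 ± 2.52 CPM. PAX7 and ZIC2 had the opposite order in differentiation 1, as given below. TNNI3, cardiac troponin I (chromosome 19, 55151767 to 55157773), rose from 0.295 ± 0.293 to 5.33 ± 1.85 CPM. SLC39A4, a zinc importer, rose from 1.86 ± 1.68 to 14.8 ± 4.08 CPM. COL3A1, a fibrillar collagen (chromosome 2, 188974320 to 189012746), was among the most abundant genes that fell, from 1186 ± 503 to 304 ± 131 CPM.

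In all, edgeR's quasi-likelihood test called 615 genes higher and 437 lower in FHS out of 15072 tested in this round, with a median absolute log2 fold change of 0.65 among the calls. The WT and FHS lines did not overlap for 1023 of the 1052 calls and for 2951 of the tested genes; chance gives full separation in 2 of the 35 ways of placing the 7 lines. A large share of the calls lay on chromosome 17, which held 353 of them among 987 tested genes (35.8%), against 699 of 14085 elsewhere (4.96%; Fisher's exact test p = 6.77e-172). Of the genes called higher, 298 (48.5%) were on chromosome 17. Without the genes of chromosome 17 the test called 247 higher and 288 lower. Leaving these genes out does not remove any effect of a chromosome 17 difference on genes elsewhere. In this round each FHS line also differed from each WT line in its level on part of chromosome 17, as given below. The calls on other chromosomes, PAX7 and ZIC2 among them, therefore do not tell genotype from that difference. The count of 1052 moved to 1582 without WT line 1, 547 without WT line 2, 394 without WT line 3, 552 without FHS line 1, 544 without FHS line 3 and 623 without FHS line 4.

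Among the 12 largest rises that met the naming rule, which asked for the same sign in both rounds, were TNNI3 and SLC39A4. SYT5, a synaptotagmin of secretory vesicles, rose by a log2 fold change of 3.16 ± 0.38 and ADGRB1, an adhesion receptor of brain, by 2.77 ± 0.24. TNNI3, SYT5 and TNNT1, which also rose, lie close together on chromosome 19, between 55132794 and 55180441. Whether their rises are separate changes was not tested. MYH14, a non-muscle myosin, rose by 3.11 ± 0.36 and CPT1A, which carries fatty acids into mitochondria, by 2.28 ± 0.27. PRICKLE3, a planar polarity gene, rose by 2.52 ± 0.41, CEND1, a neuronal differentiation gene, by 2.43 ± 0.22 and CTSZ, a lysosomal cathepsin, by 2.31 ± 0.19. The other rises of this group, FMNL1 (2.18 ± 0.36), the small nucleolar RNA host gene SNHG25 (2.17 ± 0.31) and RAB37 (2.16 ± 0.51), lie on chromosome 17. The edgeR adjusted p of the 12 ranged up to 0.0329, that of RAB37, and the smallest was 5.17e-04, that of CTSZ. In differentiation 1, with 1 WT line, SYT5 had 0.538 CPM in WT and 7.56 ± 3.91 CPM in FHS, and SLC39A4 had 4.30 and 20.7 ± 10.1 CPM. Others differed little there. MYH14 had 1.82 and 2.88 ± 1.31 CPM, SNHG25 had 30.5 and 54.1 ± 60.8 CPM, and RAB37 had 0.538 and 0.845 ± 0.388 CPM. For such genes the shared sign between rounds says little.

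The falls below are the largest among genes that met the same rule. WIF1, a secreted WNT inhibitor, fell by 3.37 ± 0.81 on the log2 scale and WNT4, a WNT ligand, fell by 3.00 ± 0.33. DLL1, a Notch ligand, fell by 2.15 ± 0.42, PITX1, a homeobox gene of jaw and hindlimb, fell by 2.11 ± 0.38 and FOXF2, a forkhead gene of palate mesenchyme, fell by 2.02 ± 0.48. MAB21L2, an eye and facial development gene, went from 12.5 ± 11.7 to 2.33 ± 1.72 CPM and KLF4 from 5.29 ± 1.78 to 1.38 ± 0.266 CPM. GNGT1 fell by 3.34 ± 0.48 and the growth arrest gene GADD45G fell by 2.97 ± 0.59. The largest edgeR adjusted p among these genes was 0.0376, that of MAB21L2. WIF1 and MAB21L2 varied widely among the WT lines, with an SD close to the mean. In differentiation 1 all genes of this paragraph but MAB21L2 were barely read in WT line 1 and in FHS. The highest of them there was GNGT1, at 0.414 and 0.321 CPM. Their shared sign between rounds therefore says little. MAB21L2 had 12.3 CPM in WT line 1 and 4.29 CPM in FHS in that round.

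**Figure D2:**
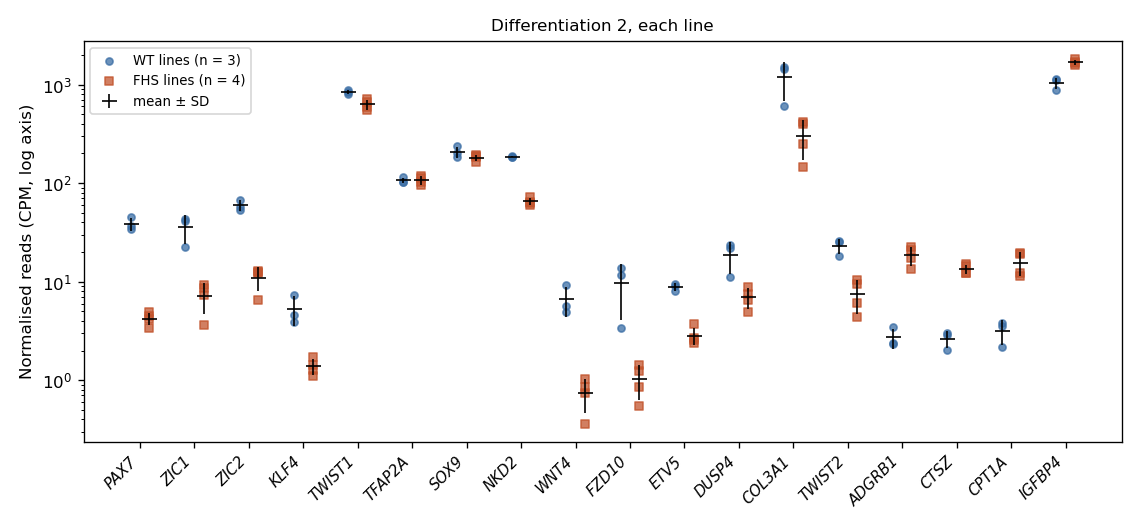
Normalised reads in CPM on a log axis for 18 named genes in each line of differentiation 2, with WT lines as blue circles (n = 3), FHS lines as orange squares (n = 4) and bars for mean ± SD. PAX7, ZIC1, ZIC2 and NKD2 were lower in each FHS line than in each WT line, while TFAP2A and SOX9 overlapped.

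The neural crest specification list had 24 tested members, of which 6 fell, 0 rose and 18 did not pass; 7 fell adjusted over the list alone. PAX7, ZIC1, ZIC2 and KLF4 fell most, and TWIST1, a regulator of mesenchymal fate, fell from 847 ± 39.7 to 631 ± 72.6 CPM (edgeR adjusted p = 0.0257). SOX9, at 207 ± 26.9 and 182 ± 13.4 CPM (edgeR adjusted p = 0.295), and TFAP2A, at 107 ± 6.13 and 107 ± 10.4 CPM (edgeR adjusted p = 0.987), did not pass. SOX9 lies on the part of chromosome 17 from 31 Mb on, described below. The median log2 fold change there was 0.49, while that of SOX9 was -0.19 ± 0.10. Camera called the neural crest specification list lower in differentiation 2 (adjusted p = 0.00346; adjusted p = 0.466 with an estimated correlation) but not without FHS line 2 (adjusted p = 0.133). The call of TWIST1 was lost when WT line 2 (log2 fold change -0.43), WT line 3 (-0.38), FHS line 1 (-0.399) or FHS line 4 (-0.45) was left out.

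Of 21 tested genes of FGF and MAPK signalling, 7 fell, 0 rose and 14 did not pass, and 12 fell adjusted over the list alone. ETV5, an ETS factor induced by FGF (chromosome 3, 186046308 to 186110318), fell from 8.84 ± 0.742 to 2.84 ± 0.585 CPM. The phosphatase gene DUSP4 fell from 18.8 ± 6.70 to 6.97 ± 1.67 CPM. ETV1 fell from 11.5 ± 1.19 to 5.11 ± 0.945 CPM and EGR1 from 5.88 ± 2.08 to 2.89 ± 0.721 CPM. Camera called the list lower (adjusted p = 1.04e-08; adjusted p = 0.283 with an estimated correlation). On the line sums, described below, the list was not called (camera adjusted p = 0.0714, median log2 fold change 0.04).

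Of 20 tested genes of WNT signalling, 5 fell, 0 rose and 15 did not pass; 7 fell and 1 rose adjusted over the list alone. The receptor gene FZD10 fell from 9.60 ± 5.53 to 1.02 ± 0.392 CPM. Among the others that fell were inhibitors of the pathway: WIF1, FRZB, which went from 102 ± 11.7 to 56.6 ± 12.0 CPM, and NKD2 (chromosome 5, 1008829 to 1038943), from 186 ± 3.34 to 65.1 ± 5.47 CPM (edgeR adjusted p = 1.55e-05). Camera called the list lower (adjusted p = 0.0017; adjusted p = 0.283 with an estimated correlation).

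In the fibrillar collagen and matrix list 2 of 23 fell, COL3A1 and the proteoglycan gene DCN (12.7 ± 6.12 to 4.25 ± 0.723 CPM), and 21 did not pass. In that list 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.481 with an estimated correlation). In the bone list 1 of 6 fell, ALPL, the alkaline phosphatase of mineralising cells, from 18.7 ± 6.08 to 9.74 ± 1.90 CPM, while 5 did not pass. There 3 fell adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.283 with an estimated correlation). RUNX2, a master factor of bone, did not pass at 2.32 ± 1.06 and 0.972 ± 0.329 CPM. In the pluripotency list 2 of 9 fell, LIN28A (41.4 ± 27.1 to 10.3 ± 6.78 CPM) and DPPA4 (10.3 ± 2.55 to 5.58 ± 1.13 CPM), and 7 did not pass. There 4 fell adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.466 with an estimated correlation).

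Camera called 2 lists higher in FHS in differentiation 2. In the list of cytoplasmic ribosomal proteins 4 of 41 rose, 0 fell and 37 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.666 with an estimated correlation). The 4 were RPL38 (log2 fold change 0.70 ± 0.09), RPL27 (0.61 ± 0.10), RPL19 (0.58 ± 0.08) and RPL23 (0.52 ± 0.10), which lie on chromosome 17. Without its genes in the lists camera gave an adjusted p of 0.0652, and without them in the whole fit it still called the list (adjusted p = 0.0188). In the list of canonical histones, whose mature transcripts mostly lack a poly(A) tail, 1 of 18 rose, HIST1H2BG (4.10 ± 1.23 to 10.7 ± 1.79 CPM). Also 1 rose adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.601 with an estimated correlation). Of the 27 lists tested, 8 were called and 0 were called with an estimated correlation between genes; fry, which tests for a common direction without reference to other genes, called 5 lists, all lower. These were FGF and MAPK signalling, WNT signalling, bone, neuron, and skeletal and cardiac muscle. Camera called 13 lists without WT line 1 and 4 without FHS line 2. With 1 line left out the calls of bone, canonical histones, cytoplasmic ribosomal proteins, neural crest specification and pluripotency could be lost, with an adjusted p of up to 0.0604, 0.248, 0.0742, 0.133 and 0.211. The direction of camera could differ from the median or mean of a list, as for clustered protocadherins (median log2 fold change 0.03, mean -0.20) and interferon response (0.23 and -0.14), which camera placed on the lower side. For the IGF and growth hormone axis camera pointed down and fry up.

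**Figure D3:**
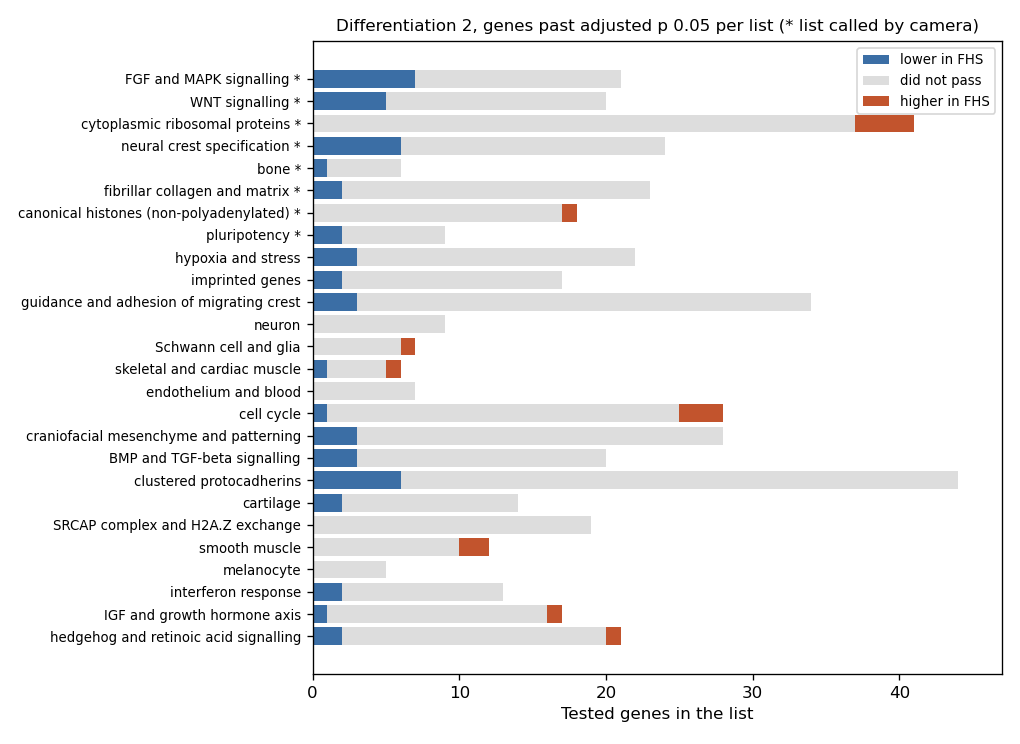
Number of tested genes per list in differentiation 2 that were lower in FHS (blue), did not pass adjusted p 0.05 (grey) or were higher in FHS (orange), with lists called by camera marked by an asterisk. The FGF and MAPK signalling list had 7 of 21 lower and the cytoplasmic ribosomal proteins 4 of 41 higher.

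The other lists were not called by camera in differentiation 2, although most held single genes that passed edgeR's test. In craniofacial mesenchyme and patterning 3 of 28 fell, PITX1, FOXF2 and TWIST2 (23.1 ± 4.23 to 7.56 ± 2.81 CPM). There 7 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.258). Of 44 clustered protocadherins 6 fell, among them PCDHGB4 (8.05 ± 6.29 to 0.355 ± 0.1 CPM) and PCDHB15 (14.7 ± 8.79 to 4.73 ± 1.47 CPM). Among these 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.518). Of 20 BMP and TGF-beta genes 3 fell, the antagonist FST (6.93 ± 3.75 to 2.60 ± 0.641 CPM), GDF10 and SMAD7. Again 3 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.469). Among 34 guidance and adhesion genes of migrating crest UNC5B, SLIT1 and EPHA2 fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.145). Among 21 hedgehog and retinoic acid genes DHRS3 and RARB fell and RARA, which lies on chromosome 17, rose. There 2 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.960).

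The growth and stress lists were not called by camera in the main fit, though some alternative fits called hypoxia and stress or imprinted genes. In the IGF and growth hormone axis IGF2 fell from 212 ± 18.6 to 153 ± 23.2 CPM and IGFBP4, which binds IGFs and lies on chromosome 17, rose from 1047 ± 134 to 1687 ± 90.1 CPM. The other 15 of 17 did not pass, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.960). IGF2 and PEG10 (703 ± 193 to 433 ± 70.3 CPM) were the 2 of 17 imprinted genes that fell, and 2 fell adjusted over the list alone (camera adjusted p = 0.117). Of 28 cell cycle genes TOP2A and BIRC5, both on chromosome 17, and CENPE rose, MCM6 fell, and the counts were 3 and 1 adjusted over the list alone as well (camera adjusted p = 0.237). FDXR, a mitochondrial reductase gene on chromosome 17, rose from 20.7 ± 2.18 to 36.0 ± 3.75 CPM and AEN, a nuclease gene, fell from 17 ± 0.511 to 10.9 ± 1.59 CPM. Of 22 hypoxia and stress genes HSPA1A, TRIB3 and the glucose transporter gene SLC2A1 fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.0859). Of 13 interferon response genes IFI44 and IFI44L fell, 2 adjusted over the list alone too (camera adjusted p = 0.747).

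Markers of other cell types moved in both directions. Of 7 Schwann cell and glia genes 1 rose, 1 adjusted over the list alone (camera adjusted p = 0.145), and ERBB3, a neuregulin receptor gene, did not pass at 1.06 ± 0.217 and 1.99 ± 0.5 CPM. The smooth muscle genes MYL9 (4.69 ± 2.00 to 9.77 ± 1.81 CPM) and LMOD1 rose, 2 of 12 and 2 adjusted over the list alone (camera adjusted p = 0.632). The cartilage genes ACAN (2.12 ± 1.45 to 0.497 ± 0.240 CPM) and COL9A3 fell, 2 of 14 and 2 adjusted over the list alone (camera adjusted p = 0.617). Of 6 skeletal and cardiac muscle genes TNNT1, which lies close to TNNI3, rose and PAX7 fell, 1 each adjusted over the list alone (camera adjusted p = 0.207). By edgeR 0 of 9 neuron genes (camera adjusted p = 0.145), 0 of 7 endothelium and blood genes (camera adjusted p = 0.218) and 0 of 5 melanocyte genes (camera adjusted p = 0.717) passed, also adjusted over the list alone. INA stood at 5.15 ± 2.39 and 2.40 ± 0.785 CPM, TIE1 at 5.89 ± 4.37 and 2.96 ± 0.847 CPM and KIT at 5.78 ± 2.25 and 3.56 ± 0.619 CPM. A further 5 lists had fewer than 5 tested genes and no list test. In them NES, a neural progenitor filament gene, and CXCR4, a chemokine receptor gene, fell. The mitochondrial genes MT-ND4 and MT-CO3 rose from 1.06 ± 0.108 to 3.12 ± 1.57 and from 2.40 ± 0.314 to 7.03 ± 2.84 CPM. Few mitochondrial reads were counted, 6.40e-04 to 0.00872 percent in the 11 libraries, which also limits the mitochondrial values below. In differentiation 2 their share separated the groups, at 6.40e-04 to 8.00e-04 percent in WT and 0.00125 to 0.00349 percent in FHS, and a difference in library composition or RNA quality was not excluded. KRT8 and HOXB7 did not pass, at 14.3 ± 3.01 and 22.6 ± 5.77 CPM and at 2.45 ± 1.49 and 0.949 ± 0.406 CPM.

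The changes on chromosome 17 followed position along the chromosome. From its start to 8 Mb, 30 of 151 tested genes fell and 0 rose, with a median log2 fold change of -0.59. Between 8 and 31 Mb, 18 of 181 fell and 1 rose, with a median of -0.32. From 31 Mb on, 297 of 655 rose and 7 fell, with a median of 0.49, and 92.2% of the tested genes had a higher value in FHS. Among the genes of this last part that did not pass the test, the median was 0.35. The WT lines did not share a level. Set against WT line 3 of differentiation 2, the median log2 ratio up to 8 Mb was -0.98 in WT line 1 and -0.24 in WT line 2, and it ranged from -0.99 to -0.88 in the 4 FHS lines of that round. From 31 Mb on, it was -0.03 in WT line 1 and 0.19 in WT line 2, and 0.51 to 0.56 in the FHS lines. WT line 1 stood at 0.47 in differentiation 1.

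**Figure D4:**
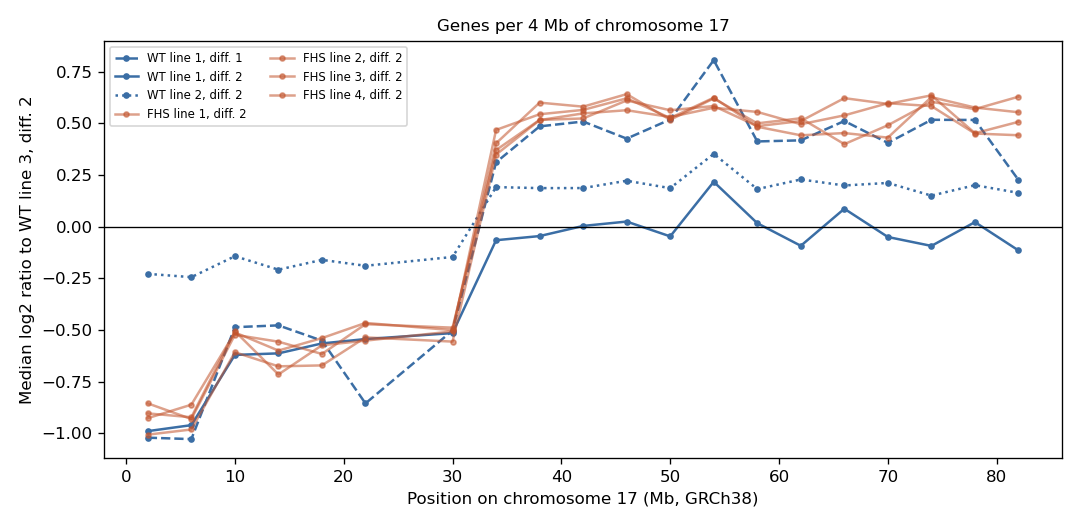
Median log2 ratio of gene counts to WT line 3 of differentiation 2 in windows of 4 Mb along chromosome 17 (GRCh38), with WT libraries in blue and FHS libraries in orange. Up to 31 Mb WT line 1 lay with the FHS lines, and from 31 Mb on only its library of differentiation 1 did.

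In differentiation 1 the comparison had WT line 1 alone against FHS lines 2, 3 and 4, and edgeR called 0 of 18165 genes, with 243 at an unadjusted p under 0.05, while DESeq2 called 21. PAX7 had 6.53 CPM in WT line 1 and 11 ± 2.53 CPM in FHS, and ZIC2 had 10.6 and 16.5 ± 4.10 CPM, the opposite order from differentiation 2. Further named genes, among them LIN28A, ACAN, UNC5B and IFI44L, also had the opposite order, as listed below. With 1 WT line its spread was taken from the FHS lines. FHS line 2 differed from FHS lines 3 and 4 by a chi-square per degree of freedom of 134 and 173, against 15.6 between lines 3 and 4. The count was 542 without FHS line 2, 11 without FHS line 3 and 4 without FHS line 4.

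Whether genotype acted differently in the rounds was tested as an interaction within lines, and edgeR called 0 of 19267 genes, with 592 at an unadjusted p under 0.05; DESeq2 called 12. The smallest p belonged to LIN28A (log2 difference between rounds -4.46 ± 0.55, edgeR adjusted p = 0.0873), followed among named genes by PAX7 (-4.01 ± 0.57, adjusted p = 0.159), UNC5B (-3.52 ± 0.56, adjusted p = 0.24) and ZIC2 (-3.08 ± 0.51, adjusted p = 0.248). None of these passed. The count was 251 without FHS line 2, 18 without FHS line 3 and 15 without FHS line 4, and 1 without the line as a block. Of the 1052 genes called in differentiation 2, 555 had the same sign in differentiation 1 (52.8%), 152 of 353 on chromosome 17 (43.1%) and 403 of 699 elsewhere (57.7%). The share on chromosome 17 does not bear on genotype. WT line 1, the only WT line of differentiation 1, stood there at -1.03, -0.52 and 0.47 in the 3 parts, beside the FHS lines of differentiation 2. From 31 Mb on it differed between rounds (0.47 and -0.03), while the other parts were alike (-0.98 and -0.56 in differentiation 2). Across the 15072 genes tested in differentiation 2, the log2 fold changes of the rounds had a Pearson correlation of 0.074 and a Spearman correlation of 0.00895. The Pearson correlation, which is across genes that are not independent replicates, was 0.0458 without FHS line 1, 0.224 without FHS line 2, 0.0486 without FHS line 3 and 0.0152 without FHS line 4.

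When the usable counts of each line were summed, so that each of the 7 lines counted once, edgeR called 0 of 16865 genes between WT and FHS, with 1444 at an unadjusted p under 0.05, and DESeq2 called 177. The rises with the smallest p, none of which passed, were EFEMP2, a gene of elastic fibres (10.6 ± 1.16 to 39.8 ± 9.54 CPM, edgeR adjusted p = 0.0964), SYT5 (0.576 ± 0.269 to 7.08 ± 2.95 CPM), CTSZ (3.48 ± 0.963 to 15.0 ± 4.12 CPM), C3orf18, PRICKLE3 and RNF208. The falls with the smallest p, which did not pass either, were PTPRN2 (2.75 ± 2.18 to 0.101 ± 0.0431 CPM, edgeR adjusted p = 0.0964), the homeobox gene DLX1 (2.89 ± 1.34 to 0.367 ± 0.0585 CPM), PLPPR3, the chemokine gene CXCL14, PCDHB15 and the surface marker gene CD24 (235.9 ± 32.9 to 88.1 ± 27.1 CPM). These 12 genes were also taken because their FHS and WT lines did not overlap. WT lines 2 and 3 and FHS line 1 entered with differentiation 2 alone, so the difference between rounds was part of the spread of the sums. It also entered the contrast, since 2 of 3 WT lines but 1 of 4 FHS lines lacked differentiation 1. The count was 502 without WT line 1 and 9 without FHS line 2, and 33 when the 11 libraries entered as separate samples with the round as a term.

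On the line sums camera called 12 of 29 lists, 9 lower and 3 higher in FHS, and 0 with an estimated correlation; fry called 0. The lower lists were craniofacial mesenchyme and patterning (median log2 fold change -0.77; adjusted p = 1.49e-06 by camera and adjusted p = 0.359 with an estimated correlation), guidance and adhesion of migrating crest, WNT signalling, neural crest specification, fibrillar collagen and matrix, bone, neuron, clustered protocadherins, and BMP and TGF-beta signalling. Of their genes, 0 passed edgeR's test over all genes, but 7 craniofacial, 5 neural crest specification and 4 WNT genes fell adjusted over the list alone. The higher lists were canonical histones (median 0.81), mitochondrially encoded genes (median 0.95) and cell cycle (median 0.16). For the other 11 of the 12 the adjusted p with an estimated correlation was 0.276 or more. Because WT held more of differentiation 2, these calls on the line sums mix genotype with the round. With libraries as samples and the round as a term, camera still called 10 of the 12. That fit has no line term, so the libraries of a line from both rounds counted as separate samples of its genotype. In it camera lost BMP and TGF-beta signalling (adjusted p = 0.0857) and cell cycle (adjusted p = 0.538). On the line sums both were also lost without chromosome 17 genes in the lists (camera adjusted p = 0.0669 and 0.052). Within differentiation 2 the craniofacial, guidance, protocadherin, BMP, neuron and cell cycle lists were not called. For cell cycle camera pointed down in that round (median log2 fold change -0.10), the opposite direction from the line sums.

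Between rounds FOXC2, a forkhead gene of cranial mesenchyme (chromosome 16, 86567251 to 86569728), rose from 0.623 ± 0.218 CPM in differentiation 1 (n = 4) to 147 ± 26.4 CPM in differentiation 2 (n = 7; log2 fold change 7.85 ± 0.25, edgeR adjusted p = 2.25e-09). CCDC85A and TMIGD3 had 0 reads in differentiation 1 and 3.32 ± 2.14 and 2.03 ± 0.393 CPM in differentiation 2, a rise of at least 68.8-fold and 44.5-fold by the 95% binomial bound on the pooled reads. FOXD1 and MEOX1 rose from 0.0387 ± 0.0531 and 0.0628 ± 0.102 CPM to 16.2 ± 18.9 and 8.73 ± 2.89 CPM.

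Among the largest falls, POU3F3, a neural POU factor, went from 168 ± 124 to 5.86 ± 4.64 CPM and the exchanger gene SLC8A3 from 11.4 ± 1.43 to 0.208 ± 0.173 CPM. AFAP1L2 fell from 38.5 ± 10.1 to 1.5 ± 0.747 CPM, the cyclooxygenase gene PTGS1 from 8.82 ± 4.14 to 0.325 ± 0.139 CPM, STC2 from 31.4 ± 11.6 to 1.58 ± 0.841 CPM and the metalloprotease gene ADAM12 from 8.77 ± 1.64 to 0.744 ± 0.914 CPM. In all, edgeR called 2239 genes higher and 2679 lower in differentiation 2 out of 17239, and with the line as a block it called 1413 higher and 1259 lower. With all 14 libraries it called 278.

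**Figure D5:**
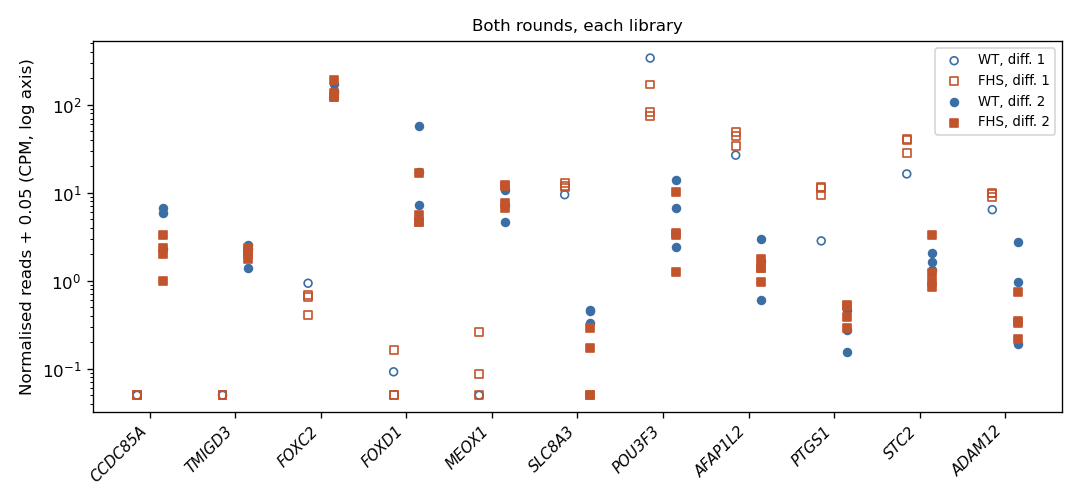
Normalised reads plus 0.05 in CPM, on a log axis, of the 11 genes named for the difference between rounds, in each library, with open symbols for differentiation 1, filled symbols for differentiation 2, blue circles for WT and orange squares for FHS. WT and FHS libraries of a round lay together for FOXC2, and each of its libraries of differentiation 2 was above each library of differentiation 1.

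Camera called 16 of 30 lists between rounds, 10 higher and 6 lower in differentiation 2, and 0 with an estimated correlation. Craniofacial mesenchyme and patterning was higher (adjusted p = 9.48e-07; adjusted p = 0.0844 with an estimated correlation). In it 18 of 33 rose and 1 fell, with 18 and 2 adjusted over the list alone, among them FOXC2, MEOX1 and PITX1. Hedgehog and retinoic acid signalling was higher (adjusted p = 6.93e-05; adjusted p = 0.0795 with an estimated correlation). Of its genes 14 of 22 rose and 1 fell, 17 and 2 adjusted over the list alone, among them GLI1 (7.76 ± 3.84 to 27.2 ± 7.89 CPM), RARB (20.8 ± 7.93 to 80.6 ± 34.3 CPM) and ALDH1A2, which makes retinoic acid. Guidance and adhesion of migrating crest was higher (adjusted p = 0.00645; adjusted p = 0.242 with an estimated correlation). There 16 of 38 rose and 8 fell, 20 and 8 adjusted over the list alone. The semaphorin receptor genes NRP1 and NRP2 rose from 10.7 ± 4.24 to 132 ± 15.2 CPM and from 16.8 ± 2.54 to 81.6 ± 28.2 CPM. BMP and TGF-beta signalling was higher (adjusted p = 0.00845; adjusted p = 0.296 with an estimated correlation). There 10 of 22 rose and 2 fell, 12 and 2 adjusted over the list alone, among them GDF10 (5.14 ± 2.17 to 75.7 ± 28.8 CPM) and TGFB1 (11.2 ± 4.13 to 67.4 ± 20.4 CPM).

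Neural crest specification was also higher in differentiation 2 (camera adjusted p = 0.0159; adjusted p = 0.296 with an estimated correlation). Among its genes 10 of 24 rose and 2 fell, 12 and 3 adjusted over the list alone, among them PAX3 (12.4 ± 7.61 to 66.3 ± 9.42 CPM), MSX2 (0.613 ± 0.268 to 14.9 ± 11.4 CPM) and KLF4. Of the melanocyte list 4 of 6 rose, 4 adjusted over the list alone, including MITF, its master factor (0.854 ± 0.571 to 4.77 ± 1.10 CPM; camera adjusted p = 0.0159; adjusted p = 0.242 with an estimated correlation). In the neural progenitor list 3 of 5 rose, 3 adjusted over the list alone, among them EMX2, a forebrain homeobox gene, from 1.95 ± 0.694 to 71.5 ± 37.8 CPM (camera adjusted p = 0.00918; adjusted p = 0.294 with an estimated correlation). Of the canonical histones 3 of 18 rose, 3 adjusted over the list alone, among them HIST1H2BG (camera adjusted p = 0.0185; adjusted p = 0.44 with an estimated correlation). KRT8 and GATA3 were the 2 of 6 epithelium and epidermis genes that rose, 2 adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.296 with an estimated correlation). Of 48 clustered protocadherins 6 rose and 2 fell, 5 and 2 adjusted over the list alone, with PCDHA1 rising from 1.01 ± 0.462 to 3.98 ± 1.44 CPM and PCDHAC2 falling from 5.23 ± 2.20 to 1.65 ± 0.509 CPM (camera adjusted p = 0.0296; adjusted p = 0.335 with an estimated correlation). Without WT line 1 the calls between rounds of neural crest specification (adjusted p = 0.19), canonical histones (0.0525), epithelium and epidermis (0.0682) and clustered protocadherins (0.0678) were lost. The last 3 were also lost without 1 of the FHS lines.

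FGF and MAPK signalling was lower in differentiation 2 (camera adjusted p = 0.00918; adjusted p = 0.335 with an estimated correlation), with 12 of 23 falling and 7 rising, 13 and 7 adjusted over the list alone. The feedback inhibitor gene SPRY4 fell from 55.3 ± 3.13 to 4.2 ± 1.56 CPM, DUSP6 from 21.6 ± 2.90 to 2.32 ± 0.841 CPM and ETV5 from 44.2 ± 4.83 to 5.25 ± 3.20 CPM, while the ligand gene FGF9 rose. Schwann cell and glia genes were lower (camera adjusted p = 0.0155; adjusted p = 0.294 with an estimated correlation), 5 of 9 falling, 5 adjusted over the list alone. ERBB3 fell from 13.6 ± 5.14 to 1.53 ± 0.595 CPM and the glial receptor gene GFRA3 from 4.75 ± 1.77 to 1.34 ± 0.275 CPM. Of the hypoxia and stress genes 12 of 23 fell and 3 rose, 13 and 4 adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.335 with an estimated correlation). LDHA fell from 338 ± 203 to 45.6 ± 12.2 CPM and PDK1 from 30.4 ± 9.41 to 5.65 ± 1.60 CPM, and JUN, an immediate early gene, rose from 72.2 ± 26.8 to 496 ± 105 CPM. Of the cytoplasmic ribosomal proteins 15 of 41 fell, 17 adjusted over the list alone, among them RPL4, from 5069 ± 923 to 3248 ± 208 CPM (camera adjusted p = 5.30e-04; adjusted p = 0.335 with an estimated correlation). Of the cell cycle genes 11 of 28 fell, 12 adjusted over the list alone, among them TYMS, which makes thymidylate, from 122 ± 27.7 to 65.5 ± 7.20 CPM (camera adjusted p = 0.00755; adjusted p = 0.335 with an estimated correlation). Of 8 mitochondrially encoded genes 4 fell, 6 adjusted over the list alone, among them MT-ND4 (camera adjusted p = 0.0296; adjusted p = 0.44 with an estimated correlation). The call of mitochondrially encoded genes between rounds was lost without WT line 1 (adjusted p = 0.223), WT line 3 or FHS line 2. The other 14 lists were not called: endothelium and blood, with an adjusted p of 0.0512, came closest, and the SRCAP complex and H2A.Z exchange list had 0.710.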

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

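The tests of the 3 patterns weighed here were chosen only after the result was seen, as were the list tests of differentiation 2 and of the rounds. The other regroupings were planned before.

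Of 102 groups of 4 lines tested for a line far from the others, 5 held one, and chance gives 5% of them. In differentiation 2, SRCAP stood at 481 CPM in FHS line 4 and at 7.72 to 11.1 CPM in the other FHS lines. FHS line 2 stood apart for ZIC2 (6.53 CPM, the others 12.1 to 12.8), ALPL (6.90 CPM, the others 10.6 to 10.8) and GATA3 (0.288 CPM, the others 4.30 to 4.88), and FHS line 3 for INA (1.23 CPM, the others 2.69 to 2.93).

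The calls on chromosome 17 may reflect a different dosage of its segments between the lines, since 92.2% of the tested genes from 31 Mb on had a higher value in FHS, called or not. Genotype alone did not account for the part up to 8 Mb, where the medians of the 3 WT lines spanned 0.976 on the log2 scale. From 31 Mb on, 1 WT library lay within the range of the FHS libraries other than that of FHS line 2 in differentiation 1, which did not decide between dosage and genotype. In the log2 fold changes of differentiation 2, a bias for gene-dense chromosomes of the size of the chromosome 17 change was not seen. The largest median of chromosomes 16, 19 and 22 was 0.0806, against 0.49 on chromosome 17 from 31 Mb on. A smaller bias was not excluded, as chromosomes 16, 19 and 22 had 20, 47 and 11 rises and 8, 16 and 11 falls. The library of FHS line 2 in differentiation 1 did stand low on these chromosomes. Its median log2 ratios to WT line 3 of differentiation 2 were -0.61, -0.91 and -0.64, while the other libraries lay between -0.0746 and 0.136. That library enters differentiation 1, the interaction, the rounds and the line sums. The counts hold no DNA data, so dosage itself was not measured.

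Low depth did not account for the abundant genes without reads in 3 libraries of differentiation 1, because 0 of the 100 genes were expected at 0 at these totals. In the same libraries 563 genes under 0.05 CPM in the other 11 stood over 20 CPM, which could arise if reads were placed on other coordinates than the annotation. Read positions were not used here, and no biological explanation was tested.

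The SRCAP count of FHS line 4 in differentiation 2 was 55.4-fold over the median of the other libraries of the round. A gain of the region was not seen, as the 14 neighbours within 200 kb had a median log2 ratio of 0.0559. The FHS genotype did not account for it either, since the other 3 FHS lines had a log2 ratio to WT of 0.0176. SRCAP sequence from outside the cells' own transcript could not be told from higher expression, because the 55.4-fold excess came without read positions.

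When the 7 lines were regrouped in the 35 possible ways, only the real grouping gave as many as the 1052 calls of differentiation 2. The highest other gave 30. This share of 1 of 35, or 0.0286, is the smallest the test can give. Chance was therefore unlikely for that count but not excluded. The real grouping also separates the lines by their level on chromosome 17 from 31 Mb on. The count thus does not tell genotype from that difference. The same holds for the calls on other chromosomes and for the lists of differentiation 2. For the line sums the real grouping gave 0 calls, which any grouping reaches, so chance was not tested there. Other groupings gave 795 (WT line 1 with FHS lines 3 and 4) and 606 (WT lines 2 and 3 with FHS line 1, the lines without differentiation 1), which points to a structure of the samples. The latter also gave 13 lists, against 12 for the real grouping, and within differentiation 2 it gave 0 calls and 7 lists. For the lists, 2 of 35 gave at least the 12 calls of the line sums (highest other 13) and 11 of 35 at least the 8 of differentiation 2 (highest other 13), so chance was not excluded. For the rounds, 1 of 100 groupings of libraries gave 4918 calls (highest other 4) and 2 of 100 gave 16 lists (highest other 16). These groupings used the fit without a line block and ignored that libraries of both rounds can come from the same line.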

How the results depend on the processing

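The fits with all 14 libraries and without chromosome 17, and the list tests of differentiation 2 and of the rounds, were chosen only after the result was seen. Where a count moved, the cause was not tested.

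On the line sums, against 0 calls, DESeq2 gave 177, no filter 392, adjusted p 0.10 gave 5, libraries as samples 33 with the round as a term and 6 without, limma voom with a random effect 7, and limma-trend 15. In differentiation 1, against 0, DESeq2 gave 21 and no filter 33. In differentiation 2, against 1052, no filter gave 2145, adjusted p 0.10 gave 1771 and the omission of chromosome 17 gave 535. For the interaction, against 0, DESeq2 gave 12, no filter 46 and adjusted p 0.10 gave 1. For the rounds, against 4918, all 14 libraries gave 278. With each line left out the counts ranged from 0 to 502 for the line sums, 4 to 542 for differentiation 1, 394 to 1582 for differentiation 2, 0 to 251 for the interaction and 3489 to 6164 for the rounds.

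Line numbers shared by WT and FHS did not clearly pair them in differentiation 2. The deviations from the mean log2 CPM of the genotype had correlations across genes of 0.252, -0.00143 and -0.0878 for numbers 1, 2 and 3. That of number 1 was above the 0.121 of FHS line 4 between its own rounds. With the number as a replicate block the count was 497 in differentiation 2 and 0 on the line sums, and 15 lists were called in differentiation 2. With the line as a block the rounds gave 2672, and without the block the interaction gave 1.

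Of the lists, 0 were called with an estimated correlation on the line sums, in differentiation 2 and in the rounds, and fry called 0, 5 and 22. With each line left out camera called 8 to 18 on the line sums, 4 to 13 in differentiation 2 and 11 to 18 in the rounds. The concordance of the rounds ranged from 0.0152 to 0.224 with each line left out and reversed to -0.0165 with all 14 libraries.

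Differentiation 1 alone, with 1 WT line, reversed the sign of these genes that had passed in differentiation 2: PAX7 (0.81), ZIC2 (0.68), LIN28A (1.54), ACAN (2.28), ALPL (0.70), FZD10 (0.25), ETV5 (0.31), EGR1 (0.15), RARB (0.17), RARA (-0.27), IGFBP4 (-0.10), IGF2 (0.60), UNC5B (1.65), EPHA2 (0.22), BIRC5 (-0.0703), MCM6 (0.19), FDXR (-0.22), HSPA1A (0.16), TRIB3 (0.40), IFI44 (1.37), IFI44L (1.64), PEG10 (0.25), PCDHGB4 (0.85) and MT-CO3 (-0.44). It also reversed genes that had not passed: HOXB7 (0.10), PAX6 (0.48), INA (0.72), NHLH1 (0.31), ERBB3 (-0.96), RUNX2 (0.61), TIE1 (1.17) and H2AFV (-0.27). These are fitted values. The difference of mean log2 CPM kept the sign for EGR1 (-0.07) and HSPA1A (-0.06) and turned it for RPL38 (-0.10), RPL27 (-0.04), RPL19 (-0.02), MT-ND4 (-0.19) and HIST4H4 (-0.15). SRCAP, which had not passed, ranged with each line left out from -0.0222 without FHS line 4 to 4.17 without WT line 2, and was -0.0247 with the line-number block. H2AFV reversed to -0.0473 with libraries as samples. TFAP2A, which had not passed, ranged from -0.0567 without FHS line 1 to 0.0537 without FHS line 2. It also reversed without WT line 1 (0.0373) or FHS line 4 (0.0145), with the stricter filter (0.00887) and with the line-number block (0.00805). All 14 libraries reversed the sign between rounds of RPS24 (0.11), RPS25 (0.22), RPL38 (0.15), RPL4 (0.35), CENPE (0.17), CDK1 (0.30), DMBX1 (-2.20) and PCDHA1 (-2.42). Of the other values of named genes, 1208 kept direction and side of the threshold in differentiation 2, 342 lost the call and 21 gained it; the counts were 165, 0 and 71 for the line sums and 939, 79 and 0 for the rounds.

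A GC correction was not run for want of a genome, nor a line-number block in differentiation 1, whose design had too few libraries. WT line 1 could not be left out of differentiation 1, the interaction or the concordance, where it was the only WT line.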

Other observations

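The values of this part were chosen only after the result was seen. CHCHD2, a mitochondrial regulator, had 0.455 and 0.146 CPM in WT line 1 in differentiations 1 and 2 and 65.2 to 142 CPM in the other usable libraries.

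The correlation of the rounds, 0.074, was reached by 17 of 34 groupings of the lines, with a median of 0.0636 and a highest value of 0.388 among the others.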
